A study of Homo sapiens with 4 samples.

How the data were processed

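SK-N-MC cells were profiled by ChIP-seq for FLI1, SSRP1 and H3K27ac, with 1 library per target and 1 input library, 4 libraries in all. Groups were taken from the sample titles. Per the series' design text, chromatin was digested with micrococcal nuclease and then sonicated before immunoprecipitation. Nuclease digestion favours nucleosome-bound fragments, so the fragments recovered can differ from those of sonicated chromatin alone.

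Per the series' design text, the authors aligned reads to hg19 with Bowtie2 at its default settings and called peaks with MACS2 against the input at a q-value threshold of 0.05. The version of MACS2 was 2.2.7.1, per the submitters' processing notes, which also name HOMER and deepTools. Filtering of duplicate reads, of multiply mapped reads or of listed artefact regions is not given in the sources used here. With default Bowtie2 settings, a read that matches several places equally well is assigned to 1 of them, which affects repeats and duplicated regions.

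The deposited peak lists were used as given, 1 per target: each holds the chromosome, start, end and name of a peak, and no height, fold enrichment, p-value or q-value. The authors called peaks in each library separately. Names that differ only by a final letter repeat 1 interval, as MACS2 writes for a peak with several summits, so each interval was counted once: 38324 FLI1 lines became 36539 peaks, 23078 SSRP1 lines 19955 and 62198 H3K27ac lines 37271. Chromosomes 1 to 22 and X were analysed. Chromosome names and lengths fitted the GRCh37 reference, and coordinates are 1-based in hg19.

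A peak was called shared when at least 20% of it, or of the peak it met, was covered, after the minimum of 20% in the series' design text. Shares carry 95% Clopper-Pearson intervals. Each was compared with 100 circular shifts of the other list within each chromosome. FLI1 and SSRP1 were compared within H3K27ac peaks by the Mantel-Haenszel odds ratio over 10 strata of H3K27ac peak width, with the Robins-Breslow-Greenland interval. Peaks are not replicates and each target has 1 library, so no p-value was computed.

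Genes came from GENCODE release 44 mapped to GRCh37, with 20090 protein-coding genes and the TSSs of their basic transcripts. A gene carried a mark when a peak met the window of 2.5 kb on each side of a TSS. The share of each of 10 gene lists was ranked among 10000 random lists of the same size, drawn from all genes or matched on H3K27ac at the TSS. A rank gives the percentage of random lists with fewer marked genes and describes these libraries only. Older symbols were matched through an NCBI gene table of GRCh38, used for names alone, by which CYR61 and CTGF became CCN1 and CCN2. PECAM1, a marker of other cell types, was not matched, which left 23 genes on that list.

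Sequence under peaks was searched for at least 4 consecutive GGAA or TTCC, and for an ETS core (CCGGAA followed by G or A, on either strand), beside the same peaks moved by 10 kb. Genes and regions named by rule were the EWS-FLI1-activated genes with all 3 marks (the first 15 in list order) and with none, any member of the fixed lists, the 10 widest FLI1 peaks shared by all 3 lists, the 10 widest SSRP1 peaks shared with FLI1 and the 5 widest SSRP1 peaks without FLI1. The rule, the gene lists, the overlap minimum and the comparisons were fixed before the data were examined, and tests chosen later are named as such where they are used. Values of some single genes on the lists are not reported here. The gene lists came from general knowledge of the field and not from these libraries.

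The functions were tested on simulated data: a planted overlap of 30.0% of 10000 peaks was recovered as 30.0%, and an odds ratio of 3.0 with confounded strata, over 40000 simulated peaks, as 2.96. Shifted placements of unrelated lists gave a mean ratio of 1.05. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, bedtools 2.31.1 and samtools 1.23.1 were used, with random seed 1.

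Alternatives were other overlap minima, autosomes only, local shifts, no width strata, TSS windows of 1 and 5 kb and runs of at least 6 GGAA. Added after the data were seen were the exclusion of chromosomes 3, 8, 10 and X, only the wider peaks of each list (at or above its median width), strata of width with 10 Mb bins or with TSS, canonical TSSs and the ETS core. The planned comparisons of stronger peaks and of lists of equal size were not run, since they need a peak strength. Read depth and signal tracks were not analysed here, and no motif discovery was run.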

Results

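Chromatin occupancy was profiled by ChIP-seq in SK-N-MC, an established Ewing sarcoma cell line. Ewing sarcoma is driven by a fusion of EWSR1 with an ETS transcription factor, most often FLI1, and the EWS-FLI1 protein binds both ETS sites and runs of the GGAA motif. The targets were FLI1, SSRP1 and acetylated lysine 27 of histone H3 (H3K27ac), a mark of active promoters and enhancers. SSRP1 and SUPT16H form FACT, a histone chaperone that loosens and rebuilds nucleosomes, and the series concerns inhibition of FACT in this tumour. Each target had 1 library, and an input library served as the authors' control. On chromosomes 1 to 22 and X (hg19), the deposited lists held 36305 FLI1 peaks, 19855 SSRP1 peaks and 37195 H3K27ac peaks, with median widths of 283, 403 and 653 bp. No replicate check was possible, so intervals in the text are 95% exact binomial (Clopper-Pearson) intervals, or intervals of an odds ratio, that cover counting error only. Read depth and peak height were not analysed here.

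SSRP1 peaks lay at promoters more often than FLI1 peaks did. A transcription start site (TSS) of a protein-coding gene lay within 2.5 kb of 46.0% of SSRP1 peaks (95% interval 45.3 to 46.7), 38.9% of H3K27ac peaks (38.4 to 39.4) and 18.2% of FLI1 peaks (17.8 to 18.6). Peaks moved to random positions on their chromosome met a TSS window in 5.46%, 5.67% and 4.69% of cases. By their midpoints, 36.7% of FLI1 peaks lay in introns outside those windows and 42.4% were intergenic, against 24.4% and 24.8% of SSRP1 peaks.

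The first comparison asked how far the sites of FACT coincided with those of FLI1 and with acetylated chromatin. Of the SSRP1 peaks, 6217 (31.3%, interval 30.7 to 32.0) were shared with FLI1 and 12039 (60.6%, 59.95 to 61.3) with H3K27ac. Of the FLI1 peaks, 6254 (17.2%, 16.8 to 17.6) were shared with SSRP1 and 10302 (28.4%, 27.9 to 28.8) with H3K27ac. Most sites where FLI1 and SSRP1 met were acetylated: 79.8% (78.7 to 80.8) of the SSRP1 peaks shared with FLI1 also met H3K27ac, against 51.9% (51.1 to 52.8) of the SSRP1 peaks without FLI1. Read from the FLI1 side, H3K27ac lay at 79.4% (78.4 to 80.4) of FLI1 peaks with SSRP1 and at 17.8% (17.3 to 18.2) of those without it. FLI1 peaks outside both other lists were the largest class, at 24716 peaks or 68.1% of the list, with a median width of 264 bp against 435 bp for FLI1 peaks shared with both.

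**Figure D1:**
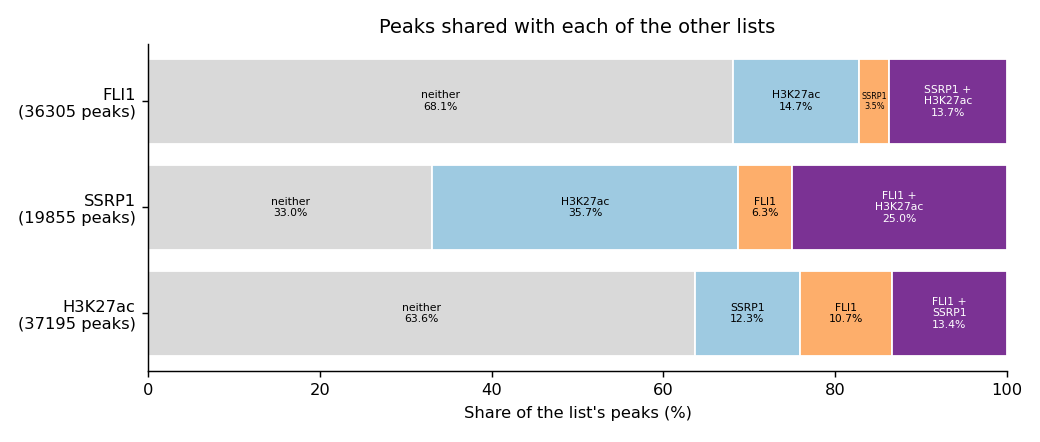
Each bar is 1 peak list (number of peaks in brackets), divided by the share of its peaks (percent, horizontal axis) that met neither of the other lists, 1 of them, or both. FLI1 peaks met neither in 68.1% of cases and SSRP1 peaks in 33.0%, while 13.7% of FLI1 peaks and 24.98% of SSRP1 peaks met both other lists.

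Over 100 circular shifts within each chromosome, the mean share of SSRP1 peaks that met FLI1 by position alone was 1.08%, so the observed share was 29.0 times higher (23.9 to 36.8 over single shifts). The ratio was 29.5 for SSRP1 with H3K27ac and 16.3 for FLI1 with H3K27ac. Shifts of only 50 to 500 kb, which keep each peak in its neighbourhood, lowered these ratios to 13.5, 12.3 and 8.14. When at least 20% of both peaks had to overlap, 40.4% of SSRP1 peaks and 16.5% of FLI1 peaks met H3K27ac, whose peaks were wider.

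The next comparison asked whether FLI1 and SSRP1 lay in the same H3K27ac peak more often than their common preference for wide ones would give. Each had to meet the H3K27ac peak, but they did not have to meet each other. Both were more frequent in wide H3K27ac peaks. In the narrowest width decile (median 303 bp) FLI1 lay in 8.28% of H3K27ac peaks and SSRP1 in 6.24%, and in the widest (median 2864 bp) in 63.1% and 71.3%. In every decile SSRP1 was more frequent where FLI1 was present: 21.4% against 4.87% in the narrowest and 81.1% against 54.4% in the widest. The Mantel-Haenszel odds ratio over the 10 deciles was 3.50 (interval 3.30 to 3.71), against 6.52 without width strata. It was 5.38 (4.93 to 5.86) among H3K27ac peaks away from a TSS and 2.93 (2.68 to 3.19) among those at a TSS.

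**Figure D2:**
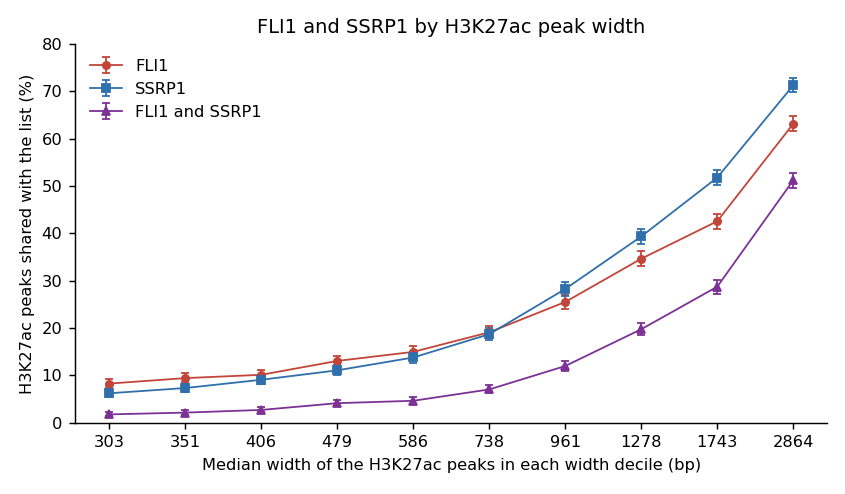
Points are the share of H3K27ac peaks (percent, vertical axis) shared with FLI1, with SSRP1 or with both, in each decile of H3K27ac peak width (horizontal axis, median width in bp, evenly spaced by decile), and bars are 95% exact binomial intervals. The share with both was 1.77% in the narrowest decile and 51.2% in the widest.

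Genes known to be activated by EWS-FLI1 carried SSRP1 at their promoters more often than other genes. Of 40 such genes, fixed before the data were examined, 33 had an SSRP1 peak within 2.5 kb of a TSS (82.5%, interval 67.2 to 92.7), against 35.8% of 20090 protein-coding genes. FLI1 lay at 25 of them (62.5%, 45.8 to 77.3), against 29.0% of all genes, and H3K27ac at 37 (92.5%, 79.6 to 98.4), against 57.9%. All 3 lay at 24 of the 40 (interval 43.3 to 75.1%), against 17.3% of all genes. The SSRP1 count was above that of 100% of 10000 random lists matched on H3K27ac at the TSS, and the FLI1 count above that of 99.8%. Here and below, lists were matched on the presence of H3K27ac and not on the width of its peak, with which both FLI1 and SSRP1 rose.

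In list order, the first 15 of the 24 genes with all 3 were NR0B1, NKX2-2, CCND1, GLI1, SOX2, PRKCB, STEAP1, ID2, CAV1, BCL11B, PPP1R1A, FCGRT, CCK, KDSR and JAK1. At NR0B1, a nuclear receptor gene on chromosome X (30322323 to 30327507), a 699 bp FLI1 peak and a 1057 bp SSRP1 peak covered a TSS. At NKX2-2, a homeobox gene on chromosome 20 (21491655 to 21494702), the SSRP1 peak of 1788 bp covered the TSS and the FLI1 peak began 430 bp from it. At STEAP1 the FLI1 peak was 998 bp wide and the SSRP1 peak 1295 bp, inside 3902 bp of H3K27ac. At FCGRT, the gene of the neonatal Fc receptor, a FLI1 peak of 2668 bp with 12 consecutive GGAA lay over a TSS. EZH2, STEAP2, VRK1, HOXD13, NPY1R and PAX7 had SSRP1 and H3K27ac without FLI1 in the window. At STEAP2 a FLI1 peak with 17 consecutive GGAA lay 3.175 kb from a TSS. H3K27ac was the only mark in the window at 6 genes: IGF1, LIPI, AURKA, GSTM4, SOX6 and CALCB. Near SOX6, a FLI1 peak with 10 consecutive GGAA, shared with SSRP1 and H3K27ac, lay 6.71 kb from a TSS. Near LIPI, a FLI1 peak lay 2532 bp from a TSS, just outside the window. UPP1 had FLI1 and SSRP1, DKK2 had SSRP1 alone, and TERT, the catalytic subunit of telomerase, was the 1 gene with none.

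**Figure D3:**
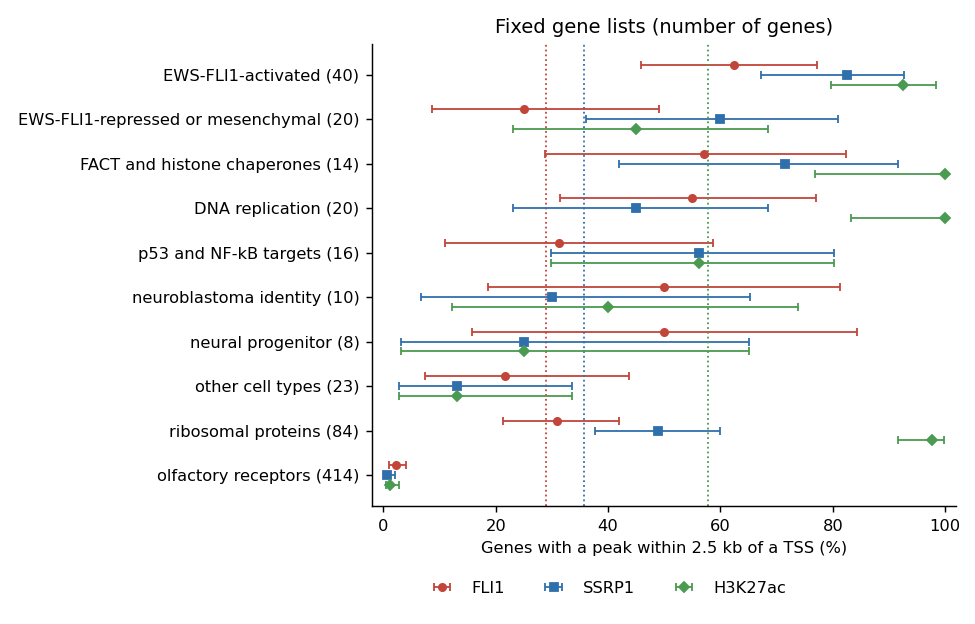
Points are the share of each fixed gene list (percent, horizontal axis, number of genes in brackets) with a FLI1, SSRP1 or H3K27ac peak within 2.5 kb of a TSS, bars are 95% exact binomial intervals, and dotted lines are the shares over all 20090 protein-coding genes. EWS-FLI1-activated genes had SSRP1 in 82.5% of cases and olfactory receptor genes in 0.725%.

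The 20 genes listed as repressed by EWS-FLI1 or as mesenchymal had a different make-up. SSRP1 lay at 12 of them (interval 36.1 to 80.9%), above 97.7% of random lists and above 99.9% of lists matched on H3K27ac. FLI1 lay at 5 (8.66 to 49.1%), or 3 with a window of 1 kb and 7 with 5 kb. H3K27ac lay at 9 (23.1 to 68.5%). FOXO1, PHLDA1, ZYX and COL1A2 carried all 3. CDKN1A, SPRY1, THBS1 and TAGLN carried SSRP1 without the other marks, and TGFBR2, IGFBP3, DKK1, NT5E and ICAM1 carried none. TGFBR2, DKK1 and ACTA2 of this list lie on chromosome 10 or on chromosome 3 before 120 Mb, where FLI1 and SSRP1 peaks were sparse.

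Among 14 genes of FACT and other histone chaperones, H3K27ac lay at all 14, SSRP1 at 10 and FLI1 at 8. SSRP1 itself, ASF1A, ASF1B, CHAF1A, NASP and HIRA carried all 3, while SUPT16H, the partner of SSRP1 in FACT, carried H3K27ac alone. The counts for SSRP1 and FLI1 were above 83.4% and 80.3% of lists matched on H3K27ac. DNA replication genes were acetylated in 20 of 20 cases, with FLI1 at 11 and SSRP1 at 9, above 82.8% and 13.4% of matched lists. MCM4, MCM6, MCM7, PCNA, CDC45 and RRM2 carried all 3. Of the 84 cytoplasmic ribosomal protein genes, 82 had H3K27ac, 41 SSRP1 and 26 FLI1, and the FLI1 count was above only 1.60% of matched lists. The SSRP1 count was above 15.7% of matched lists. With a window of 5 kb SSRP1 rose to 59 genes, above 99.4%, and FLI1 to 36, above 20.8%, while with 1 kb SSRP1 fell to 33, above 0.520%.

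Targets of p53 and NF-kB had SSRP1 at 9 of 16 genes, among them CDKN1A and BBC3, which had neither FLI1 nor H3K27ac, and FLI1 at 5 and H3K27ac at 9. SSRP1 was above 95.4% of matched lists there, or 82.8% with a window of 5 kb, and above 92.4% of random lists from all genes. Of 10 neuroblastoma identity genes, FLI1 lay at 5, SSRP1 at 3 and H3K27ac at 4, but with a window of 1 kb FLI1 lay at only 2. Within 2.5 kb, PHOX2A, GATA3 and DBH had FLI1 alone, and MYCN and TFAP2B had all 3. Of 8 neural progenitor genes, FLI1 lay at 4, SSRP1 at 2 and H3K27ac at 2, with FLI1 alone at SOX1, NES and OLIG2, and with a window of 1 kb FLI1 lay at 2. Markers of other cell types were mostly bare: 16 of 23 had no mark, including the T cell genes CD3D and CD3E and the liver gene ALB. FLI1 lay at 5 of them, SSRP1 at 3 and H3K27ac at 3, and with a window of 5 kb FLI1 lay at 8 and SSRP1 at 6, while canonical TSSs, chosen after the data were seen, gave 3 for FLI1. Olfactory receptor genes had FLI1 at 9 of 414, SSRP1 at 3 and H3K27ac at 5. Windows of 1 and 5 kb gave 2 and 16 for FLI1 there, and 5 kb gave 9 for H3K27ac.

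Over all protein-coding genes, SSRP1 was most frequent at genes that carried both FLI1 and H3K27ac. Each mark was assigned separately, so the marks of a gene can lie at different TSSs. The number of TSSs per gene was not held alike. SSRP1 lay at 71.1% (interval 69.8 to 72.4) of 4898 genes with FLI1 and H3K27ac, at 42.7% (41.6 to 43.9) of 6726 with H3K27ac alone, at 27.6% (24.8 to 30.6) of 934 with FLI1 alone and at 7.57% (6.98 to 8.19) of 7532 with neither.

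The widest peaks stood in place of the strongest, since the lists give no peak strength. The widest SSRP1 peak shared with FLI1 covered 8821 bp of CCND1, the gene of cyclin D1, on chromosome 11 (69457327 to 69466147), and began 1353 bp from the nearest TSS. It was followed by peaks at IRS2 on chromosome 13 (110433451 to 110438876, 5426 bp) and near SAMD11 on chromosome 1 (851418 to 856830, 5413 bp). The other 7 lay in an intron of GPSM1 on chromosome 9 (139239454 to 139244457), upstream of SAMD11 (845091 to 850070) and in one of its introns (874749 to 879492), and at the TSS windows of SMIM47 on chromosome 19 (51296782 to 51301517), ARHGDIA on chromosome 17 (79823446 to 79827676), ZNF703 on chromosome 8 (37552428 to 37556370) and RAB26 on chromosome 16 (2198138 to 2202069). Of these 10 peaks, 7 lay at a TSS, 8 met H3K27ac and 0 held a run of at least 4 GGAA. The 5 widest SSRP1 peaks without FLI1 lay at GAPDH on chromosome 12 (6643703 to 6648519, 4817 bp), 41.0 kb from FCGR2A on chromosome 1 (161430484 to 161434225), at FTL on chromosome 19 (49467949 to 49471551), at CTXN1 on chromosome 19 (7989937 to 7993002) and at DIPK1B on chromosome 9 (139615522 to 139618384).

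**Figure D4:**
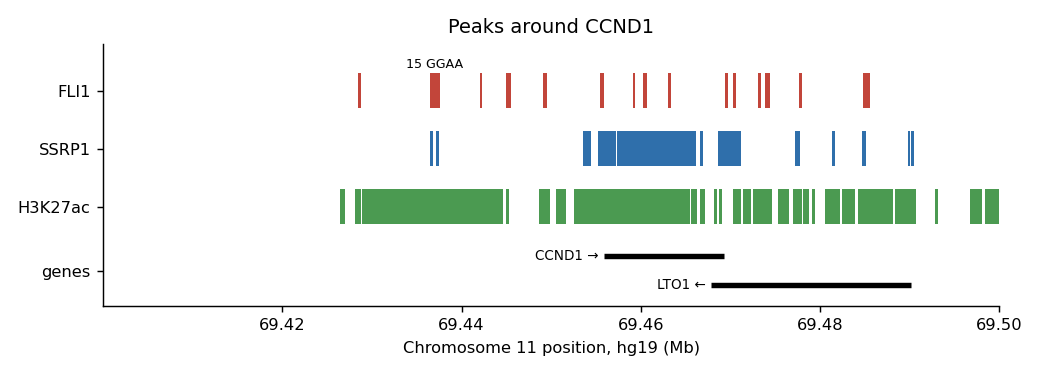
Map of chromosome 11 from 69400001 to 69500000 (hg19, position in Mb on the horizontal axis) with FLI1, SSRP1 and H3K27ac peaks as boxes to scale and the genes CCND1 and LTO1 as lines with arrows for their strand. The 100000 bp held 15 FLI1, 12 SSRP1 and 26 H3K27ac peaks, and the FLI1 peak with 15 consecutive GGAA is labelled.

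Around CCND1, SSRP1 covered 17153 bp of the 100000 bp mapped, H3K27ac 54564 bp and FLI1 6574 bp. A FLI1 peak of 1117 bp upstream of the gene (69436462 to 69437578) held 15 consecutive GGAA at 69436923 to 69436982 and lay 18.3 kb from the nearest TSS. SSRP1 peaks flanked this repeat on both sides, at 69436478 to 69436835 and at 69437178 to 69437490, within an H3K27ac peak of 15676 bp.

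The last comparison asked which FLI1 peaks held the motif run bound by EWS-FLI1. At least 4 consecutive GGAA, on either strand, occurred in 978 FLI1 peaks (2.69%, interval 2.53 to 2.87), against 0.187% of the same peaks moved by 10 kb. The run occurred in 18 SSRP1 peaks (0.0907%, 0.0537 to 0.143), against 0.237% after the move, and in 0.731% of H3K27ac peaks (0.647 to 0.823), against 0.774%. Wide FLI1 peaks held it most often, at 25.9% (22.4 to 29.6) of those over 900 bp and 0.821% (0.702 to 0.954) of those up to 300 bp. An ETS core, a motif added after the data were seen, occurred in 8.56% of FLI1 peaks (8.27 to 8.85) against 2.18% after the move. In the other lists, whose peaks were wider, it occurred in 11.9% of SSRP1 peaks against 4.27%, and in 18.2% of H3K27ac peaks against 6.21%. At a TSS it occurred in 24.8% (23.7 to 25.8) of FLI1 peaks, 17.8% of SSRP1 peaks and 34.2% of H3K27ac peaks. The core was thus not confined to FLI1 peaks, though its excess over moved peaks was largest there.

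Among the 10 widest FLI1 peaks shared by all 3 lists, 8 held a GGAA run. These lay at FCGRT on chromosome 19 (50014347 to 50017014, 12 repeats), in an intron of LINGO1 on chromosome 15 (78029923 to 78032425, 16), 178 kb from TAFA5 on chromosome 22 (49266804 to 49269110, 16), 238 kb from GFRA2 on chromosome 8 (21405272 to 21407528, 11), 5.89 kb from MYL10 on chromosome 7 (101278467 to 101280691, 16), in an intron of CHAT on chromosome 10 (50855668 to 50857864, 17), 2.45 kb from STAR on chromosome 8 (38010915 to 38012916, 13) and 69.1 kb from OLFM1 on chromosome 9 (138048610 to 138050539, 12). The other pair lay 66.8 kb from C1QTNF3-AMACR on chromosome 5 (34191448 to 34193714) and 21.2 kb from EIF2B2 on chromosome 14 (75446154 to 75448420).

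FLI1 peaks with a GGAA run away from a TSS were often acetylated, and their overlap with SSRP1 turned on that. Of 920 such distal peaks, 62.7% (interval 59.5 to 65.9) met H3K27ac and 21.1% (18.5 to 23.9) met SSRP1, against 17.6% (17.1 to 18.0) and 10.8% (10.4 to 11.2) of 28769 distal FLI1 peaks without the run. Peak width was not held alike in these shares, and distal peaks with the run were wider (median 479.5 bp against 274 bp). Wider FLI1 peaks met H3K27ac more often, at 49.7% of all those over 400 and up to 600 bp. How much of the difference in acetylation goes with width was therefore not separated. Among acetylated distal FLI1 peaks the order for SSRP1 was the opposite. SSRP1 lay at 190 of 577 with the run (32.9%, 29.1 to 36.9) and at 41.4% (40.05 to 42.8) of 5057 without it. Among those without H3K27ac, SSRP1 lay at 4 of 343 with the run (1.17%, 0.319 to 2.96) and at 4.26% (4.01 to 4.52) of 23712 without it. This order turned on what was held alike. The odds ratio of SSRP1 for peaks with the run was 0.656 (0.549 to 0.784) within acetylation strata and 0.276 (0.225 to 0.338) with peak width added. Within strata of acetylation and GC content it was 1.28 (1.05 to 1.56). With width, GC content and acetylation held alike together, a test chosen after the result was seen, it was 0.516 (0.406 to 0.657).

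FLI1 peak density differed between chromosomes far more than that of H3K27ac on a few of them. Chromosome 8 held 31.4 FLI1 peaks per Mb, against a median of 11.8 over the chromosomes, while chromosome 10 held 1.79 and chromosome X 1.12. SSRP1 peaks numbered 8.65 per Mb on chromosome 8, 1.57 on chromosome 10 and 1.06 on chromosome X, with a median of 6.81, and H3K27ac peaks 14.3, 8.26 and 5.78, with a median of 12.3. FLI1 and SSRP1 were also sparse on parts of other chromosomes, picked after the data were seen: chromosome 16 from 40 Mb held 2.48 FLI1, 2.36 SSRP1 and 10.5 H3K27ac peaks per Mb, and chromosome 17 before 20 Mb held 2.55, 3.85 and 15.8. CDT1, GINS2, CDH1 and CDH5 of the gene lists lie in the former. Leaving out chromosomes 3, 8, 10 and X, a choice made after the data were seen, gave 30.2% of SSRP1 peaks shared with FLI1 and kept those parts of chromosomes 16 and 17.

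**Figure D5:**
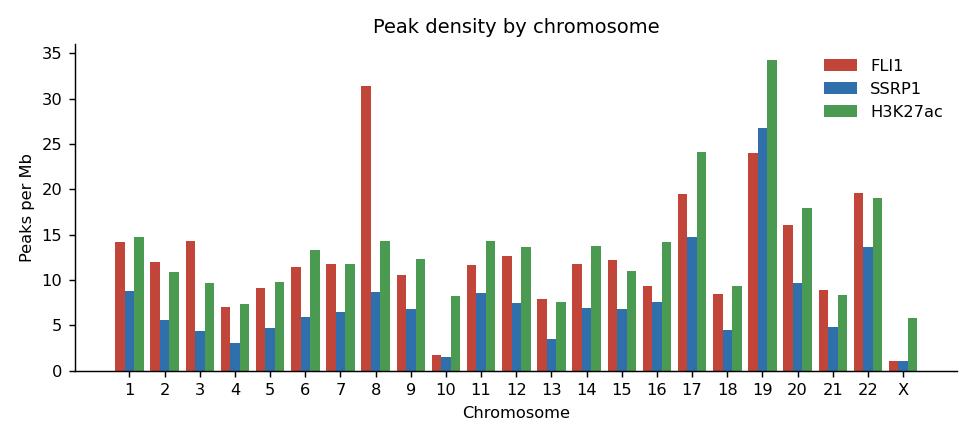
Bars are the number of FLI1, SSRP1 and H3K27ac peaks per Mb (vertical axis) on each chromosome (horizontal axis, hg19), with 1 library per target and no error bars. FLI1 reached 31.4 per Mb on chromosome 8 and 1.12 on chromosome X.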

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

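Peaks on contigs that are not placed on a chromosome lay outside the comparisons above, where they form a signal not otherwise described. FLI1 had 226 such peaks, SSRP1 93 and H3K27ac 73, and 1 contig of 162 kb held 43, 19 and 24 of them. Per Mb, the density on these contigs was 3.09 times that of the main chromosomes for FLI1, 2.33 times for SSRP1 and 0.975 times for H3K27ac. Filtering of multiply mapped reads or of artefact regions is not given, so how reads were placed may affect these densities, which was not tested.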

How the results depend on the processing

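No alternative turned the direction of the odds ratio or of a ratio to shifted placements, but most shares of overlapping peaks moved beyond their counting error and the ranks of some gene lists turned. An overlap of 1 bp gave 33.0% of SSRP1 peaks with FLI1, and 18.1% and 28.9% of FLI1 peaks with SSRP1 and with H3K27ac. For SSRP1 with FLI1, SSRP1 with H3K27ac, FLI1 with SSRP1, FLI1 with H3K27ac, and FLI1-SSRP1 shared peaks with H3K27ac, in that order, an overlap of 50% of either peak gave 27.1%, 59.1%, 15.1%, 26.7% and 78.7%, and 20% of both peaks gave 29.3%, 40.4%, 15.9%, 16.5% and 55.3%, where a narrow peak inside a wide H3K27ac peak no longer counts by construction. Autosomes alone kept all 5 shares and the odds ratio within their intervals. The odds ratio of 3.50 moved to 6.52 without width strata, and local shifts gave ratios to shifted placements of 13.5, 12.3 and 8.14. Among alternatives chosen after the data were seen, leaving out chromosomes 3, 8, 10 and X gave 30.2% for SSRP1 with FLI1 and 18.5% and 30.5% for FLI1 with SSRP1 and with H3K27ac. The wider peaks of each list, at or above its median width, gave 33.6%, 64.7%, 18.7% and 33.3% for those shares of single lists, in the same order, and an odds ratio of 2.84, and strata of width with 10 Mb bins or with TSS gave 3.27 and 3.89. A run of at least 6 GGAA occurred in 2.51% of FLI1 peaks, and the ETS core in 8.56%. TSS windows of 1 and 5 kb and canonical TSSs left the 3 shares of EWS-FLI1-activated genes within their intervals, but at 5 kb SSRP1 at ribosomal protein genes went from above 15.7% to above 99.4% of matched lists, and at 1 kb FLI1 at neuroblastoma genes went from above 86.05% to above 25.9% of random lists. Except for the overlap of both peaks, the cause was not tested. The stronger part of each list and lists of equal size were not run, since the lists give no strength. No paired analysis was possible because each target has 1 library, and depth was not analysed, so a missing peak shows only that none was called.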

Other observations

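The widest acetylated regions, listed after their values were seen, all carried FLI1 and SSRP1. All 10 of the widest H3K27ac peaks met both, and 6 held a run of at least 4 GGAA. These counts were not separated from the length of the peaks, with which FLI1 and SSRP1 rose. Over all H3K27ac peaks, the run was no more frequent than after the move by 10 kb (0.731% against 0.774%). The widest covered 25447 bp on chromosome 14 (102991996 to 103017442), 15.9 kb from ANKRD9, and 4 of the 10 lay at a TSS, those of PLEC on chromosome 8 (145010225 to 145033881), BAHCC1 on chromosome 17 (79368077 to 79387241), TNS1 on chromosome 2 (218866090 to 218882893) and MDFI on chromosome 6 (41603628 to 41620278). The widest acetylated FLI1 peaks with a GGAA run and no SSRP1, also picked after their values were seen, lay 133 kb from MYOM2 on chromosome 8 (2125703 to 2127539, 19 repeats), 13.3 kb from CBLC on chromosome 19 (45266352 to 45267833, 10 repeats) and 229 kb from FZD8 on chromosome 10 (36160691 to 36162063, 15 repeats).

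In the paragraphs that follow, the tests on chromosomes and the test of width, acetylation and GC content together were chosen after the result was seen. The statement that GGAA runs met SSRP1 less often was narrowed to peaks of like acetylation after the values were seen, while its other tests were written before theirs.

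SSRP1 met distal FLI1 peaks with a GGAA run less often than others of like acetylation, with an odds ratio of 0.656 (0.549 to 0.784) within H3K27ac strata, although without strata it was 2.21 (1.88 to 2.60). FLI1 peak width and acetylation do not account for this, since the odds ratio within strata of both was 0.276 (0.225 to 0.338). Within strata of GC content and acetylation it was 1.28 (1.05 to 1.56), so GC content may account for it. With width added as well it was 0.516 (0.406 to 0.657). GC content remains open, since the order depended on whether width was held alike. Acetylated distal FLI1 peaks had a median GC content of 49.7% with the run and 56.5% without it. The repeats had a median of 52 bp in peaks of median width 606 bp, so they made up a small part of such a peak. Reads that cannot be placed inside the repeat would leave SSRP1 beside it as often as beside other peaks. The ratio of the shares with SSRP1 within 1 kb was 0.809 (0.737 to 0.889), just under the limit of 0.9 set beforehand. These shares, 44.7% and 55.3%, were compared without holding width or GC content alike, so the ratio cannot exclude such reads. On the repeat itself such reads stay open: in acetylated distal FLI1 peaks SSRP1 covered 11 of 577 repeats and lay beside 41.2% without covering them, and H3K27ac covered only 26.7% (23.1 to 30.5), in line with lost reads or with a lack of nucleosomes, which was not tested, although FLI1 peaks, by which the repeats were picked, covered all 577, so calls across them were possible.

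Chromosome 8 held an excess of FLI1 peaks outside H3K27ac and SSRP1, at 2.75 times the median chromosome per H3K27ac peak, so more acetylated sequence does not account for it. For SSRP1 peaks outside the other lists the same ratio was 1.06, so that list showed no like excess. Both ratios are per H3K27ac peak, a number that copy number could also raise. They therefore cannot exclude copy number. On chromosomes 10 and X, where FLI1 was sparse, SSRP1 was sparse too, at 0.177 times the median, which is consistent with copy number, or the input control, acting alike on both lists. Densities on chromosome 3 rose across 120 Mb, a position chosen after the data were seen. They went from 2.30 to 32.7 per Mb for FLI1, 1.37 to 8.91 for SSRP1 and 5.90 to 15.5 for H3K27ac. The rise was uneven in each list. Bins of 10 Mb held 304 H3K27ac peaks from 120 Mb, 57 to 96 between 130 and 180 Mb, then 260 and 243. The same bins held 197, 24 to 56, then 136 and 147 SSRP1 peaks, and 548, 149 to 282, then 438 and 504 FLI1 peaks. On chromosome 3 from 120 Mb, FLI1 peaks outside the other lists numbered 1.67 per H3K27ac peak. Chromosome 8 held 1.72, and the median was 0.626. For SSRP1 that block held 0.178, against a median of 0.183. GGAA runs occurred in 1.29% of FLI1 peaks in that block and 1.44% on chromosome 8, against a median of 2.74%. The share was 16.5% on chromosome 10 and 17.8% on chromosome X. Copy number was not measured here. It stays open for chromosome 8 and chromosome 3 from 120 Mb, as does an effect that differs between the FLI1 and SSRP1 libraries.

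The 24716 FLI1 peaks outside H3K27ac and SSRP1 were narrow, and 4.75% (4.48 to 5.02) held an ETS core or a GGAA run. The count was 2.58 times (2.31 to 2.87) that of the same peaks moved by 10 kb, which were not matched on GC content. A GGAA run occurred in 1.44% against 0.129% after the move. Calls with no more such runs than nearby sequence therefore do not account for the whole class. An ETS core occurred in 3.36% against 1.71%. H3K27ac peaks without FLI1 or SSRP1 also held the core in excess (10.3% against 3.88%), as did SSRP1 peaks outside the other lists (4.94% against 3.89%). The core alone therefore does not mark FLI1 binding. For a core or a run, the share in FLI1 peaks within H3K27ac or SSRP1 was 24.7% and the ratio to moved peaks 7.08 (6.38 to 7.85). In the outside class on chromosome 8 that ratio was 1.94 (1.44 to 2.61). FLI1 binding outside called H3K27ac and SSRP1 peaks may make up part of the class and background calls another part. These peaks give no strength by which to part them, and whether their chromatin was open or closed was not measured.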
